A study of Arabidopsis thaliana with 8 samples.

How the data were processed

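Transcript levels were measured on 8 Agilent arrays, each hybridized in 2 colours with RNA of the poly(A) polymerase mutant paps1-1 and of its wild type, Arabidopsis thaliana accession Ler. 4 arrays held inflorescences from plants of 30 days, without open flowers, and 4 held whole seedlings with their roots. Mutant seedlings were harvested at 11 days and wild-type seedlings at 9 days, per the labels so that leaf development matched, so a gap of 2 days goes with genotype in seedlings. All plants grew at 21 °C. In each tissue the mutant was labelled with Cy5 on 2 arrays (replicates 1 and 2) and with Cy3 on the other 2 (replicates 3 and 4). Every array had its own wild-type RNA, so no control sample was shared. The arrays of a tissue lay on 1 slide, so slide and tissue cannot be told apart for the difference between tissues, while the genotypes were compared within each array.

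Per the file headers, the scanner files came from Feature Extraction 10.7.3.1. They hold the median intensity of each spot and of its local background in both colours, with no normalization, beside a processed intensity from which background, spatial trend and dye bias had been removed by that software. The deposited log ratio of the scanner files is the log10 of red over green processed intensity, as checked on the values. The deposited value table of the series holds log2 ratios in which the authors had already turned each array to mutant over wild type, as its correlation across probes with red over green of the normalized scanner signals showed, which was between 0.802 and 0.906 on the 4 arrays with the mutant in Cy5, and between −0.889 and −0.908 on the 4 others. Its median per array lay between −0.02 and 0.02. The submitters' processing notes list limma without a version, and the background correction and normalization behind that table are not given in the sources used here. The chemistry of the labelling, such as the primer, is not given in those sources either. In a poly(A) polymerase mutant it would matter for what the signal means.

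The analysis started from the scanner files. The plan named the mean spot signal, which these files do not hold, and the median spot signal was used in its place. Each array had 39102 spots, of which 1417 were controls, and 37478 different probes that were not controls; 23 of these were spotted 10 times and averaged. Signals were background corrected with normexp (offset 50) and normalized within each array by loess, with control spots and spots flagged as outliers given no weight, in limma 3.58.1 under R 4.3.3 with the data.table package (version 1.17.8). Flagged spots were left out. Loess sets the typical log ratio of each array to 0, so every change is relative to the other transcripts on the array. A probe was kept if it was well above background on all 4 arrays of at least 1 genotype in 1 tissue and measured on at least 6 arrays. The probes named 25665 loci, and the brightest kept probe stood for its locus, which left 21446 loci tested. The files name no gene models or genome build, so no positions are given. Symbols came from a reference table that held 25449 of the loci on the array and lacked 216. The 11242 probes without a locus were not used in the comparisons.

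The signal over background, as medians per array, ranged from 2.63 to 4.94 in red and from 3.33 to 5.48 in green, and between 57.3% and 64.2% of spots were well above background. No spot was saturated. The number of arrays limits the precision of every value.

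All 8 arrays were fitted together with limma, with 1 coefficient of mutant over wild type per tissue and a dye term per gene, which left 5 residual degrees of freedom; empirical Bayes moderation added 4.86. The comparisons were mutant against wild type in inflorescences, the same in seedlings, and the difference of both effects, seedling minus inflorescence. Log2 ratios are given with moderated standard errors (SE), and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The same fit was tested on simulated data, in which it recovered 97.0% of 1.5-fold changes in inflorescences and 98.5% in seedlings, 77.6% and 88.1% of the smaller simulated changes, and 81.3% of differences between tissues; 6.15%, 6.01% and 5.18% of the calls were false. The simulation changed 200 of 21446 genes in inflorescences and 230 in seedlings, with independent noise added to normalized values. The real fit called 53.7% and 57.9% of genes, so these rates need not hold for it, and the normalization was not tested. The correlation between tissues is across genes, which are not independent replicates.

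Gene lists, 28 in number, were tested with camera at a preset correlation of 0.01 over the 21332 genes measured on every array, with adjustment over the lists within each comparison. Camera with an estimated correlation and fry, which asks only whether the genes of a list move on balance one way, were run beside it. The lists cover poly(A) polymerases, 3′ end processing, salicylic acid and jasmonate defence, growth regulators, flower and meristem identity, markers of tapetum, pollen, root, seed and photosynthetic tissue, the clock, responses to cold, heat and iron shortage, secondary metabolism, and the SAUR, Aux/IAA, expansin, XTH, WRKY, CRK, GST, histone, cyclin and ribosomal families. Families were matched on symbols and synonyms. As a result the Aux/IAA list also holds ARF19, MP and NPH4, the CRK list holds the calcium-dependent-kinase relatives CRK1 and CRK3, and the ribosomal list holds plastid members. The lists of salicylic acid defence and SAUR genes were chosen knowing that the study had reported on such genes in these samples.

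Named genes followed a rule. Per tissue, it took the 4 poly(A) polymerase genes, the 12 highest and 12 lowest log2 ratios among called genes with the same sign on all 4 arrays, and up to 4 members of each list with the smallest adjusted p among those called, or 2 where none was called. For the tissue difference it took the 8 highest and 8 lowest among called genes whose arrays did not overlap between the tissues. Lists, comparisons, the tests of genes and lists, the rule and the alternatives were chosen before the data were examined, except for a test against a change of 1.5-fold, which was chosen after seeing that over 50% of genes passed. The tests of explanations, the further iron genes, the families by symbol prefix, the loci on chromosome 2 and the random lists matched on signal were chosen after the main results had been seen, some of them before their own results, as said with them.

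The alternatives varied the background correction, the normalization within and between arrays, the filter on dim probes, the treatment of flagged spots, the value per gene, the dye term, the moderation, a block for replicate number and the source (the software's log ratio or the value table), and left out each array in turn. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 under Python 3.11.15. Transcript isoforms, poly(A) tail lengths and poly(A) sites were not measured by these probes.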

Results

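The comparisons concern PAPS1, one of the nuclear poly(A) polymerases of Arabidopsis, which add the poly(A) tail to messenger RNA. They ask which transcripts differ in measured signal between paps1-1 mutants and wild type in inflorescences and in seedlings. Whether a ratio reflects transcript level alone was not tested, since the labelling primer is not known. Each tissue had 4 arrays (n = 4), and each array set mutant against wild type of that tissue, with the dyes exchanged on 2 of them. Log2 ratios correlated across genes between arrays of a tissue with r of 0.789 to 0.905 in inflorescences and 0.701 to 0.896 in seedlings, and with r of 0.369 to 0.536 between arrays of different tissues. Every log2 ratio below is mutant over wild type ± SE, relative to the other transcripts on the array.

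PAPS1 transcript (AT1G17980) was measured at a log2 ratio of 0.10 ± 0.05 in inflorescences (adjusted p = 0.117) and 0.002 ± 0.05 in seedlings (adjusted p = 0.973). PAPS2 (AT2G25850) and PAPS4 (AT4G32850, listed as nPAP) did not pass in either tissue. Their log2 ratios were 0.03 ± 0.07 and 0.11 ± 0.07 in inflorescences and 0.04 ± 0.07 and 0.13 ± 0.07 in seedlings, and the 2 PAPS2 probes spread from −0.32 to 0.04 there. PAPS3 (AT3G06560) fell by 0.15 ± 0.04 in inflorescences (adjusted p = 0.00999), a call that ended without inflorescence replicate 2, with normexp offset 0 and with median centring, and it was not above background in seedlings. As a list, the 4 polymerases did not shift (adjusted p = 0.910 in inflorescences and 0.641 in seedlings).

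In inflorescences, the highest ratio was that of PCC1 (AT3G22231), a pathogen-responsive gene under clock control, which was 23.0-fold higher in the mutant (log2 ratio 4.52 ± 0.18, adjusted p = 1.61e-07). LURP1 (AT2G14560), named for its induction by the oomycete Hyaloperonospora, rose by 2.71 ± 0.18 on the log2 scale. The pathogen-induced lipid acyl hydrolase PLA2A (AT2G26560) rose by 2.58 ± 0.12, and PCR1 (AT1G14880), named for cadmium resistance, by 2.98 ± 0.34. The urea transporter DUR3 (AT5G45380) rose by 2.68 ± 0.06. The lowest ratios were those of JAL23 (AT2G39330), a jacalin-related lectin, which fell by 3.15 ± 0.10, and MBP1 (AT1G52040), a myrosinase-binding protein, which fell by 2.64 ± 0.06. THI2.1 (AT1G72260), a thionin induced by jasmonate, fell by 2.60 ± 0.09. BGLU18 (AT1G52400), a β-glucosidase of the endoplasmic reticulum, fell by 2.12 ± 0.10, and CYP81F4 (AT4G37410), an enzyme of indole glucosinolate modification, by 2.09 ± 0.06. Each of these genes had the same sign on all 4 arrays.

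Of the 28 genes for EDS1 and salicylic acid defence, 20 rose and 1 fell in inflorescences (20 and 2 adjusted over the list alone). The list's median log2 ratio was 0.86, and its median on the single arrays lay between 0.62 and 0.94. Besides PCC1, the salicylic acid-linked transcription factor gene WRKY54 rose by 1.89 ± 0.10. BGL2, which encodes the pathogenesis-related glucanase PR2, rose by 2.02, ACD6 by 2.16 and the susceptibility gene DMR6 by 2.13. The regulators EDS1 and PAD4 rose by 0.70 and 0.91. PR1, at 0.42, did not pass (adjusted p = 0.264). SAG101, the partner of EDS1, fell by 0.30. The shift passed camera (adjusted p = 3.14e-07; adjusted p = 0.705 with an estimated correlation). The study had picked such genes on these samples, so the counts are not independent evidence of their direction.

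Cysteine-rich receptor-like kinases and glutathione transferases also shifted up in inflorescences. Of 33 kinase genes, 19 rose and 5 fell (the same numbers adjusted over the list alone), among them CRK5 at 1.78 ± 0.05 and CRK10 at 1.22 ± 0.05 (adjusted p = 0.00154; adjusted p = 0.705 with an estimated correlation). Of 40 glutathione transferase genes, 21 rose and 2 fell (22 and 2 adjusted over the list alone). GSTF2 was at 1.71 ± 0.16 and GSTF12, which serves flavonoid transport, at 1.39 ± 0.09 (adjusted p = 0.00237; adjusted p = 0.705 with an estimated correlation). Xyloglucan endotransglucosylases, which cut and rejoin cell wall polymers, had 15 of 31 members higher and 3 lower, with the same numbers adjusted over the list alone (adjusted p = 0.0205; adjusted p = 0.741 with an estimated correlation). XTH25 rose by 1.41 ± 0.14.

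Jasmonate response and SAUR genes shifted down in inflorescences. Of 20 jasmonate genes, 11 fell and 1 rose, also when adjusted over the list alone, with a median log2 ratio of −0.25. VSP1, a vegetative storage protein gene, fell by 1.90 ± 0.09, the biosynthesis gene LOX2 by 1.00 ± 0.13 and the repressor genes JAZ7 and TIFY7 (JAZ9) by 1.28 and 0.57. LOX3, a lipoxygenase gene, was the member that rose, at 0.90 ± 0.09. The call (adjusted p = 0.0205, and adjusted p = 0.771 with an estimated correlation) ended with the software's log ratio, with normexp offset 0, with median centring and with the deposited value table. There the adjusted p was 0.0609 to 0.147 and the median −0.34 to −0.28. Of 66 SAUR genes, which respond early to auxin, 32 fell and 2 rose, also when adjusted over the list alone, with a median of −0.20 (adjusted p = 0.000322; adjusted p = 0.771 with an estimated correlation). SAUR79 fell by 0.90 ± 0.06 and SAUR16 by 0.68 ± 0.06. The study had reported on SAUR genes in these samples, so this count is not independent evidence, and whether the probes tell near-identical SAUR genes apart was not tested.

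Heat shock, photosynthesis and expansin genes lay just outside the threshold of camera in inflorescences, and passed fry (adjusted p = 0.000670, 0.0348 and 0.00682). Of 9 heat shock genes, 5 rose and 1 fell (adjusted p = 0.0537), with HSP70 at 1.32 ± 0.07. Of 47 nuclear photosynthesis genes, 22 fell and 11 rose (adjusted p = 0.0573), with PSAG at −1.13 ± 0.08. Their median lay at −0.02 and −0.01 on the arrays with the mutant in Cy5 and at −0.45 and −0.34 on those with the mutant in Cy3. Of 28 expansin genes, 11 rose and 5 fell (adjusted p = 0.0623), with EXPB1 at 1.03 ± 0.10. Adjusted over the list alone, the counts were the same except for 23 photosynthesis genes lower. The heat shock list passed in 13 of the alternative settings, the photosynthesis list in 7 and the expansin list in 5.

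Other lists did not pass camera in inflorescences, though members changed. With fry, the lists of flowering genes (adjusted p = 0.00651), WRKY genes (0.0202) and ribosomal proteins (0.0457) passed as higher and that of 3′ end processing (0.00456) as lower. Among genes for flower identity and flowering time, 10 of 23 rose and 3 fell (adjusted p = 0.162). The flowering promoter FT rose by 1.61 ± 0.11, the MADS-box genes SEP2 and SEP1 by 0.60 and 0.55 and AGL20, also named SOC1, by 0.56, while the repressor genes FLC, SVP and MAF1 fell by 0.39, 0.40 and 0.40. Of 17 genes for 3′ end processing, 6 fell and 3 rose (adjusted p = 0.359). The nuclear poly(A)-binding protein genes PABN3 and PABN2 fell by 0.97 ± 0.05 and 0.38, and the cleavage endonuclease gene CPSF73-I by 0.44 ± 0.04, while the cleavage factor gene CFIM25 rose by 0.74. Markers of other cell types went both ways, with 7 of 17 tapetum genes higher and 5 lower (adjusted p = 0.831) and 2 of 9 mature pollen genes higher and 2 lower (adjusted p = 0.831). In the tapetum list the median was −0.11 and the test pointed up. Of 12 clock genes, 6 rose and 2 fell (adjusted p = 0.213), with ELF4 at 1.14 ± 0.15 and LHY at 0.80 ± 0.11. Of 12 cold response genes 4 rose (adjusted p = 0.167), among them COR15B at 1.34 ± 0.13, and of 15 glucosinolate genes 6 fell and 2 rose (adjusted p = 0.273). Adjusted over the list alone, the counts of these lists were the same except for 6 tapetum genes lower and 3 cold genes higher.

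Over all loci, limma called 11512 of 21446 changed in inflorescences, 5611 higher and 5901 lower, and the median absolute log2 ratio was 0.17. The split depended on the normalization, since 48.7% of the calls were higher, against 39.0% of 8842 with median centring. Of the 11512 calls, 260 were at least 2-fold higher and 103 at least 2-fold lower. Against a change of 1.5-fold, a test chosen after seeing the data, 346 passed as higher and 216 as lower. Of the 28 lists, 6 shifted with the preset correlation and 13 with fry, and none with an estimated correlation, where the smallest adjusted p was 0.705. Without inflorescence replicate 4 the number of lists was 10.

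**Figure D1:**
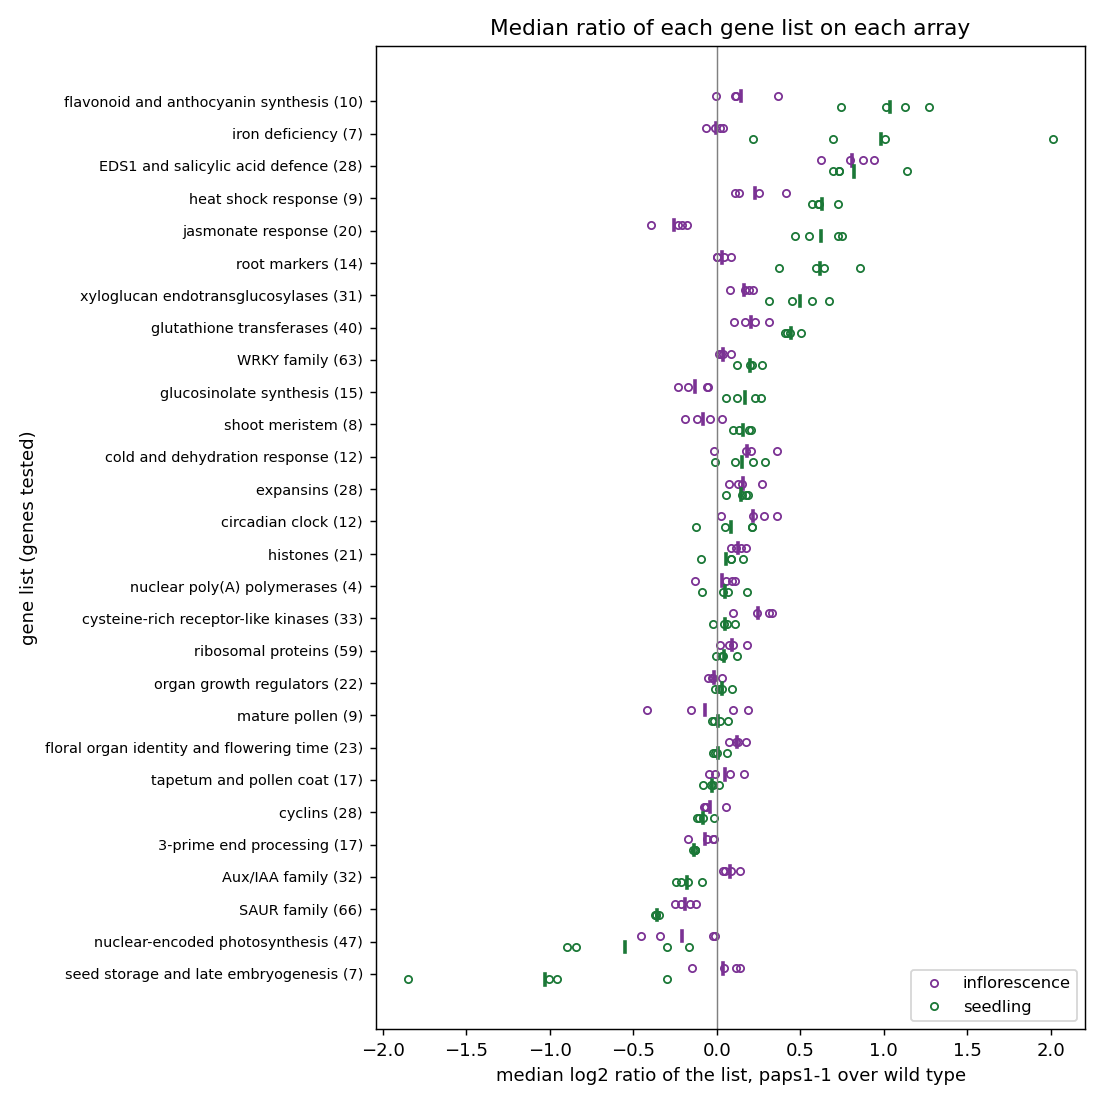
Median log2 ratio of mutant over wild type for each gene list on each of the 4 inflorescence and 4 seedling arrays (points), with the mean of the 4 array medians (ticks), on a log2 axis. The EDS1 and salicylic acid list lay between 0.62 and 1.14 on all 8 arrays, and the jasmonate list lay below 0 on the inflorescence arrays and above 0 on the seedling arrays.

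In seedlings, 2 iron-linked regulator genes were among the 12 highest ratios and the seed genes PER1, OLEO2 and TIP3;1 among the 12 lowest, with mutants 2 days older than wild type. BHLH100 (AT2G41240), a transcription factor gene induced by iron shortage, was 26.3-fold higher (log2 ratio 4.72 ± 0.08, adjusted p = 1.03e-09), and its relative BHLH101 (AT5G04150) rose by 3.31 ± 0.10. NATA1 (AT2G39030), a jasmonate-induced acetyltransferase gene, rose by 4.06 ± 0.20. AIG1 (AT1G33960), named for its induction by the effector avrRpt2, rose by 3.49 ± 0.21, and PAD3 (AT3G26830), which completes camalexin synthesis, by 3.41 ± 0.22. PCR1 rose by 3.42 ± 0.34 and the chitinase-like gene AT2G43570 by 2.86 ± 0.14. On seedling replicate 1, AIG1 and PCR1 stood at 2.48 and 2.35, below 3.72 to 3.91 and 3.65 to 3.84 on the other 3 arrays. The lowest ratios were those of AT3G16670 and AT4G33720, at −3.25 ± 0.08 and −3.25 ± 0.07. PER1 (AT1G48130), a peroxiredoxin of seeds, fell by 2.34 ± 0.08, the oleosin gene OLEO2 (AT5G40420) by 2.02 ± 0.12 and the seed aquaporin gene TIP3;1 (AT1G73190) by 1.94 ± 0.08. For AT4G23420, at −2.07 ± 0.32, a further probe gave 0.05.

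Genes of the EDS1 and salicylic acid, WRKY, glutathione transferase and heat shock lists shifted up in seedlings, where the medians of root markers and photosynthesis genes stood at 0.62 and −0.54 and age also differed. Of the 28 genes for EDS1 and salicylic acid, 26 rose and 2 fell, also when adjusted over the list alone, with a median of 0.81 (adjusted p = 1.07e-07; adjusted p = 0.465 with an estimated correlation). WRKY70 rose by 2.47 ± 0.14, the cell wall-associated kinase gene WAK1 by 2.46 ± 0.11, PCC1 by 2.33 ± 0.18 and the flavin monooxygenase gene FMO1 by 2.07, and PR1 by 1.92. SAG101 and the immune receptor gene SNC1 fell by 0.34 and 0.45. This list was picked on these samples and is not independent evidence of its direction. In the WRKY family 34 of 63 members rose and 12 fell (35 and 12 adjusted over the list alone), with WRKY18 at 1.38 ± 0.09 (adjusted p = 0.00447; adjusted p = 0.465 with an estimated correlation). Of 40 glutathione transferase genes 25 rose and 6 fell (26 and 7 adjusted over the list alone), with GSTF7 at 2.97 ± 0.11 and GSTF6 at 2.79 ± 0.07 (adjusted p = 0.000113; adjusted p = 0.396 with an estimated correlation). Of 9 heat shock genes 8 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.000934; adjusted p = 0.261 with an estimated correlation). HSP70 was at 1.31 ± 0.07 and HSP101 at 0.56 ± 0.05.

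Jasmonate and flavonoid genes shifted up in these seedlings, beside the same medians of 0.62 for root markers and −0.54 for photosynthesis genes and the gap in age. Of 20 jasmonate genes 16 rose and 4 did not pass, also when adjusted over the list alone, with a median of 0.68 (adjusted p = 3.30e-06; adjusted p = 0.432 with an estimated correlation). LOX2 rose by 2.08 ± 0.13, the synthesis gene OPR3 by 1.09 ± 0.07, the defensin gene PDF1.2c by 2.05 and VSP1 by 0.96 ± 0.09. Whether the probes tell PDF1.2c from PDF1.2 and PDF1.2b, which also rose, was not tested. All 10 flavonoid and anthocyanin genes rose, also when adjusted over the list alone, with a median of 1.01 (adjusted p = 1.95e-06; adjusted p = 0.465 with an estimated correlation). F3H rose by 1.55 ± 0.08, DFR by 1.53, LDOX by 1.18 ± 0.09 and the regulator PAP1 by 0.74 ± 0.11.

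Of 7 iron deficiency genes 4 rose in seedlings, also when adjusted over the list alone: bHLH38, at 2.45 ± 0.16, bHLH39, at 1.71 ± 0.10, BHLH100 and the root iron transporter gene IRT1, at 0.89 ± 0.23, with the root markers at a median of 0.62. The ferritin gene FER1, at 0.08, and FRU (FIT), at −0.07, did not pass. The list's call (adjusted p = 0.0220; adjusted p = 0.465 with an estimated correlation) ended with the strict filter, under which every channel had to be above background (adjusted p = 0.751). IRT1, which is also on the list of root markers, ranged from −0.06 to 2.01 over the 4 arrays and lost its call with median centring, and a further IRT1 probe gave 0.08. bHLH39 stood at 2.28 on seedling replicate 1 against 1.44 to 1.57 on the others.

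Photosynthesis genes shifted down and root markers up in the mutant seedlings. Of 47 nuclear photosynthesis genes 36 fell and 4 rose, also when adjusted over the list alone, with a median of −0.54 (adjusted p = 1.07e-07; adjusted p = 0.465 with an estimated correlation). RBCS2B, for the small subunit of Rubisco, fell by 1.33 ± 0.07 and the photosystem gene PSAD-2 by 0.93 ± 0.05, while PSBR rose by 0.42. The median was −0.30 and −0.16 on the arrays with the mutant in Cy5 and −0.89 and −0.84 on those with the mutant in Cy3. Of 14 root markers 9 rose and 1 fell, also when adjusted over the list alone, with a median of 0.62 (adjusted p = 0.00302; adjusted p = 0.566 with an estimated correlation). SHV2 of root hairs rose by 1.10 ± 0.09 and MYB66 (WEREWOLF), which sets hairless cells apart, by 0.57 ± 0.05, a call that median centring ended, while SHR fell by 0.19. The strict filter, which also drops genes that are dim in inflorescences, ended the root call (adjusted p = 0.503). Seed storage genes had 4 of 7 members lower and 3 that did not pass, also when adjusted over the list alone, with a median of −0.83 (adjusted p = 0.0330; adjusted p = 0.598 with an estimated correlation). This call ended without seedling replicate 1 or 4, with the software's log ratio, with normexp offset 0, with median centring, without a filter on dim probes and with the deposited value table, at adjusted p of up to 0.472. OLEO1 fell by 1.40 ± 0.19, EM1 by 0.83 and GEA6 by 0.69.

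SAUR and Aux/IAA genes shifted down and xyloglucan endotransglucosylase genes up in seedlings, where the median of the root markers stood at 0.62 and age also differed. Of 66 SAUR genes 41 fell and 6 rose, also when adjusted over the list alone, with a median of −0.34 (adjusted p = 1.51e-06; adjusted p = 0.465 with an estimated correlation). SAUR16 fell by 1.61 ± 0.06, SAUR22 by 1.41 ± 0.07 and SAUR23 by 1.23 ± 0.06. As in inflorescences, this count is not independent evidence. Of 32 genes in the Aux/IAA list 16 fell and 4 rose, also when adjusted over the list alone (adjusted p = 0.0133; adjusted p = 0.602 with an estimated correlation), and median centring moved the list past the threshold, to an adjusted p of 0.0536. ATAUX2-11 fell by 1.08 ± 0.05, IAA7 by 1.01 ± 0.06 and SHY2 by 0.92 ± 0.06. Of 31 xyloglucan endotransglucosylase genes 25 rose and 6 did not pass (26 rose when adjusted over the list alone), with XTH5 at 1.53 ± 0.07 (adjusted p = 5.19e-07; adjusted p = 0.261 with an estimated correlation). Expansin genes went both ways, with 13 of 28 higher and 9 lower (14 and 9 adjusted over the list alone; adjusted p = 0.475).

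The remaining lists did not pass camera in seedlings. With fry, the lists of shoot meristem (adjusted p = 0.00347), glucosinolate (0.0106), cysteine-rich receptor-like kinase (0.0165) and cold response genes (0.0309) passed as higher, and those of 3′ end processing (0.000897) and cyclins (0.0495) as lower. Of 17 genes for 3′ end processing 8 fell and 3 rose (adjusted p = 0.173), with PCFS4 at −0.69 ± 0.06, PABN3 at −0.68 ± 0.05 and the FIP1-type factor gene FIPS3 at −0.50 ± 0.06. Of 22 growth regulators 5 rose and 5 fell (adjusted p = 0.475), with the coactivator gene AN3 at 1.17 ± 0.09 and ARF2 at −0.51. Of 8 shoot meristem genes 4 rose and 1 fell (adjusted p = 0.218), with STM at 0.48 ± 0.08. The floral repressor gene FLC fell by 1.06 ± 0.06 in a list of which 4 of 23 fell and 1 rose (adjusted p = 0.993). COR15A rose by 1.41 ± 0.10 in the cold list, of which 6 rose and 6 did not pass (adjusted p = 0.227), and the clock list had 4 of 12 higher and 2 lower (adjusted p = 0.852). Of 15 glucosinolate genes 6 rose and 2 fell (adjusted p = 0.177), and of 33 cysteine-rich receptor-like kinases 11 rose and 8 fell (adjusted p = 0.444). Histone genes, with 8 of 21 higher and 6 lower, cyclin genes, with 5 of 28 higher and 13 lower, and ribosomal protein genes, with 26 of 59 higher and 12 lower, had adjusted p of 0.993, 0.241 and 0.255. The histone genes HTB4 and HIS4 fell in both tissues, by 0.98 and 0.61 in inflorescences and by 0.95 and 0.68 in seedlings. None of the 9 pollen genes passed in limma, with AGP6 at 0.10 (adjusted p = 0.993 for the list). In the tapetum list (adjusted p = 0.993), DRL1 rose by 0.32 ± 0.10, a call that ended with median centring and without seedling replicate 2, 3 or 4. Adjusted over the list alone, the counts of these lists were the same except for 9 genes of 3′ end processing lower, 3 flowering genes lower and 0 tapetum genes higher.

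**Figure D2:**
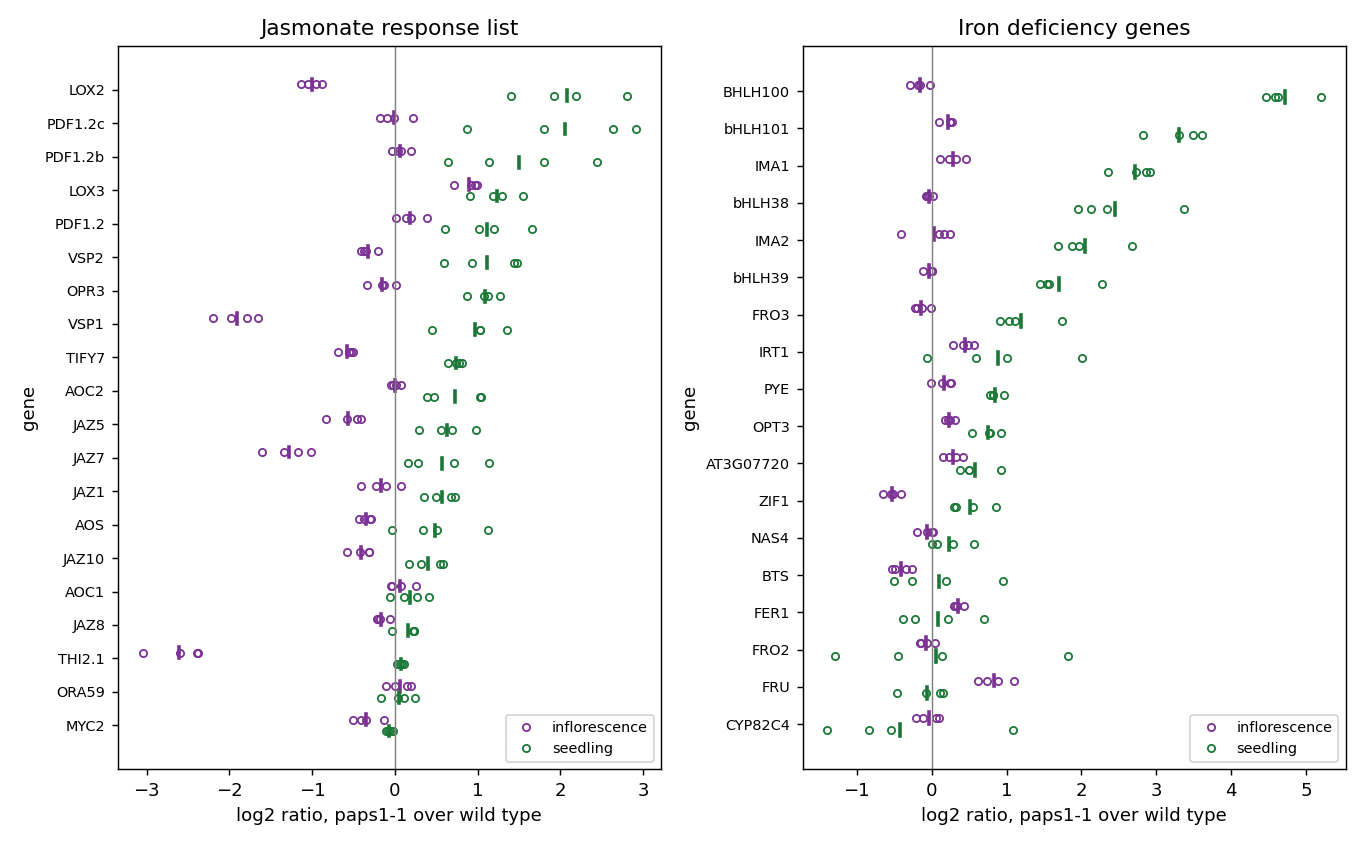
Log2 ratios of mutant over wild type on each array (points) and as fitted (ticks) for single jasmonate genes (left) and for the 7 iron deficiency genes with 11 further iron genes (right), on log2 axes, with inflorescences and seedlings in separate colours. BHLH100 lay at 4.72 in seedlings and at −0.16 in inflorescences, and VSP1 at 0.96 and −1.90.

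Over all loci, limma called 12408 changed in seedlings, 6131 higher and 6277 lower. The split depended on the normalization here too, since 49.4% of the calls were higher, against 32.4% of 10833 with median centring. Of the 12408 calls, 413 were at least 2-fold higher and 155 at least 2-fold lower. In the added test against a 1.5-fold change, 566 passed as higher and 317 as lower. Of the 28 lists, 13 shifted with the preset correlation, 19 with fry and none with an estimated correlation, where the smallest adjusted p was 0.261. The gap in age went with genotype on every seedling array, so the data hold no seedling value for genotype alone.

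Genotype effects in the 2 tissues were compared to ask where they were shared and where they differed. The jasmonate list had the smallest adjusted p of all lists, with 17 of 20 genes higher in seedlings minus inflorescences and 3 that did not pass (18 higher when adjusted over the list alone). Their median difference, seedling minus inflorescence, was 1.06 (adjusted p = 3.31e-11; adjusted p = 0.517 with an estimated correlation). LOX2 differed by 3.08 ± 0.18, VSP1 by 2.87 ± 0.13 and THI2.1 by 2.67 ± 0.13. The same direction held for BGLU18 at 3.44 ± 0.14, MBP1 at 3.15 ± 0.08 and JAL23 at 3.14 ± 0.14, the last of which stood at −0.01 in seedlings. Flavonoid genes followed, with 9 of 10 higher in the difference, also when adjusted over the list alone, and a median of 1.03 (adjusted p = 2.90e-07; adjusted p = 0.527 with an estimated correlation). PAP1 was lower in mutant inflorescences, at −1.03, and higher in mutant seedlings, at 0.74. Root markers were also higher in the difference, with a median of 0.45, and the age gap went with genotype in seedlings.

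Differences of single genes at the top were those of BHLH100 at 4.88 ± 0.12, NATA1 at 4.08 ± 0.28, AT4G12490 at 3.76 ± 0.21 and BHLH101 at 3.09 ± 0.14. Among the lowest differences were AT3G16670 at −3.26 ± 0.11, AT4G33720 at −3.18 ± 0.10, DUR3 at −2.49 ± 0.09, HVA22B at −2.42 ± 0.11 and the peptide gene RALFL11 at −2.38 ± 0.14. AT3G16670 and AT4G33720 had the lowest ratios in seedlings, while DUR3 was among the genes that rose most in inflorescences. The flowering gene AGL20 rose in inflorescences and fell in seedlings, by 0.42. The EDS1 and salicylic acid list did not pass for a difference, with 11 genes higher and 8 lower, also when adjusted over the list alone, and a median of 0.02 (adjusted p = 0.895). Members differed, as with DMR6 at −1.46, PCC1 at −2.19 ± 0.25 and FMO1 at 1.48.

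Photosynthesis genes were lower in the difference, with 29 of 47 lower and 2 higher, also when adjusted over the list alone (median −0.34, adjusted p = 2.90e-07; adjusted p = 0.527 with an estimated correlation). The Aux/IAA list, with 16 of 32 lower and 2 higher (18 and 2 adjusted over the list alone), had an adjusted p of 1.14e-05 (adjusted p = 0.527 with an estimated correlation). AXR3 (IAA17) was at 0.49 in inflorescences and −0.18 in seedlings. SAUR genes had 27 of 66 lower and 10 higher (30 and 12 adjusted over the list alone; adjusted p = 0.00347; adjusted p = 0.570 with an estimated correlation). Cysteine-rich receptor-like kinases had 16 of 33 lower and 5 higher, also when adjusted over the list alone (adjusted p = 0.00292; adjusted p = 0.527 with an estimated correlation). Xyloglucan endotransglucosylases had 15 of 31 higher and 1 lower (15 and 3 adjusted over the list alone; adjusted p = 0.00347; adjusted p = 0.527 with an estimated correlation), a call that the strict filter ended. Root markers had 7 of 14 higher and 7 that did not pass (8 higher when adjusted over the list alone; adjusted p = 0.00119; adjusted p = 0.527 with an estimated correlation), a call that median centring and the strict filter ended. Seed storage genes had 5 of 7 lower and 1 higher, also when adjusted over the list alone (adjusted p = 0.0193; adjusted p = 0.537 with an estimated correlation), a call that the software's log ratio and the absence of a filter ended. Glucosinolate genes had 7 of 15 higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.0193; adjusted p = 0.537 with an estimated correlation), a call that ended without inflorescence replicate 2 and without seedling replicate 2. CYP79B3 stood at −0.75 in inflorescences and 0.68 in seedlings, and IMS2 at 0.06 and 1.08.

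Across the 21446 loci the effects in the 2 tissues correlated with Pearson r = 0.545 and Spearman rho = 0.589, with a covariance of 0.0749. Genes are not independent replicates, so no p is given. Of 7735 genes called in both tissues, 3317 were higher in both and 3705 lower in both, where independent calls would have given 1604 and 1727. Another 354 were higher in inflorescences and lower in seedlings, and 359 the reverse, where independent calls would have given 1642 and 1687. Both tissues share 1 probe and 1 estimate of the spread per gene, so calls need not be independent even where the effects are. The effects differed between tissues for 6908 genes, 3501 with the larger ratio in seedlings and 3407 in inflorescences. With median centring the number was 2939, and 36.4% of them had the larger ratio in seedlings, against 50.7%. That share also lay under 50% with the software's log ratio (46.2%), normexp offset 0 (48.2%), the strict filter (48.1%) and the deposited value table (49.3%). Against a difference of 1.5-fold, a test chosen after seeing the data, 354 genes passed. Slide and tissue cannot be told apart in the comparison of the tissues.

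**Figure D3:**
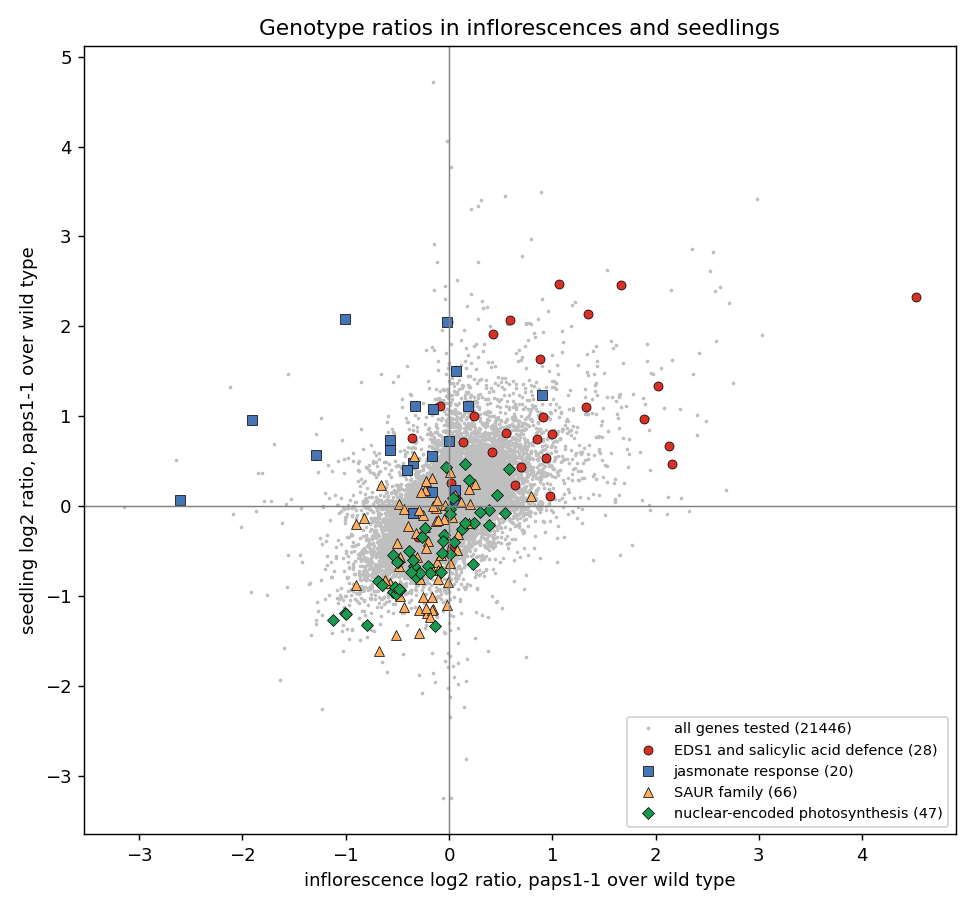
Log2 ratio of mutant over wild type in seedlings (vertical axis) against inflorescences (horizontal axis) for 21446 loci (grey), with the members of 4 gene lists in colour. Defence genes lay mostly at the upper right and jasmonate genes mostly above the diagonal, and the correlation across genes was 0.545.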

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

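The tests of age for the defence and the photosynthesis genes and the test of the root share were chosen after their results had been seen, and the other tests before.

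Effects in inflorescences and seedlings differed for 6908 genes by the test of the difference. The 8 arrays were also split into 4 and 4 in the other ways that the dyes allow. The highest count was then 0, and 1 of the 34 splits, the real one, gave as many genes, a share under 0.05. The other splits leave the real tissue difference in the residual spread, which lowers their counts, so chance is not excluded by them. Nor can the splits tell tissue from slide. For the 11512 genes changed in inflorescences and the 12408 in seedlings, 1 of 8 orientations of the 4 arrays, the real one, gave as many and the highest other count was 0, but 8 orientations are too few for a share under 0.05.

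The jasmonate list was lower in mutant inflorescences and higher in mutant seedlings, with a median difference of 1.06. The list calls were lost with an estimated correlation (adjusted p = 0.771 in inflorescences, 0.432 in seedlings and 0.517 for the difference). That in inflorescences was also lost in 4 processing settings, at adjusted p of 0.0609 to 0.147 and medians of −0.34 to −0.28. A dye bias that differs between the slides would give opposite signs in the 2 dye orientations, but the median differences were 0.84 with the mutant in Cy5 and 1.19 with the mutant in Cy3, and 19 and 20 of the 20 genes were positive. The highest median difference of 10000 random lists matched on mean signal was 0.271. Loess had already set the typical log ratio at each signal to 0 on every array. These lists therefore show only that other genes of like signal did not move with the list after normalization, and cannot decide on a bias that goes with signal. The inflorescence side came from plants of 1 age and held no root. The age gap and root share of the seedlings could not act there by design. The list's medians of −0.39 to −0.18 on its 4 arrays therefore cannot decide on either for the seedlings. For the seedling side, the age gap and a larger share of root stay open, with root markers at a median of 0.62 there. For the difference, the tissue itself also stays open, and so does the slide, which cannot be told apart from the tissue.

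Defence genes of the EDS1 and salicylic acid list were higher in both tissues, calls that were lost with an estimated correlation (adjusted p = 0.705 and 0.465). In inflorescences, from plants of 1 age, the median was 0.86, so the rise there came without an age gap. Whether inflorescences of both genotypes at that age were at the same stage of development was not tested. The age gap of the seedlings could not act on inflorescences by design, so their value cannot decide on age as a cause of the rise in seedlings, where the median was 0.81. Random lists matched on mean signal had a median of −0.002 in each tissue and reached 0.293 at most. Loess had set the typical log ratio at each signal to 0 on every array, so a median near 0 was fixed in advance. The random lists therefore cannot decide on a bias that goes with signal. As the study had picked the list on these samples, its lead over random lists is no evidence that the rise is biological. An effect of genotype stays open, and whether the mutant plants had met a pathogen was not tested.

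In seedlings, photosynthesis genes were lower and root markers higher in the mutant, calls that were lost with an estimated correlation (adjusted p = 0.465 and 0.566), the root call also with the strict filter. A larger share of root in the mutant seedlings would raise root markers alike. Of the 10 markers above background other than SCR and SHR, 1, PLT2 at 0.12, lay more than 2 SE under 50% of the list's median. That is too few to decide, so a larger share of root cannot be told apart from a change within organs. MYB66, kept among the 10, was also called changed in inflorescences, so the 10 were not shown to be absent from shoots. SCR and SHR, at −0.01 and −0.19, were left out as expressed in shoots only after their values had been seen, and with them 3 of 12 markers lay that low, which would argue against a larger share of root as the whole cause. The age gap cannot be told apart either. In inflorescences, of plants of 1 age, the photosynthesis median was −0.18 (adjusted p = 0.0348 with fry in limma) against −0.54 in seedlings. These values exclude neither a part due to age nor a part that is not. The median of root markers was 0.04 (adjusted p = 0.995 with fry) against 0.62, but inflorescences hold no root, so their value cannot decide on age or root share. The biological explanation, an effect of genotype on these genes in seedlings, stays open and untested.

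Other lists whose shift differed between the tissues, as median seedling minus inflorescence, were root markers at 0.45, seed storage at −1.04, glucosinolate synthesis at 0.0805, flavonoid and anthocyanin synthesis at 1.03, SAUR at −0.18, Aux/IAA at −0.23, xyloglucan endotransglucosylases at 0.28, cysteine-rich receptor-like kinases at −0.25 and photosynthesis at −0.34. These calls were all lost with an estimated correlation (adjusted p = 0.527 to 0.570), that of root markers also with median centring and the strict filter, of seed storage with the software's log ratio and without a filter, of xyloglucan endotransglucosylases with the strict filter, and of glucosinolate synthesis without inflorescence replicate 2 or seedling replicate 2. Named genes with the highest differences were BHLH100 at 4.88, NATA1 at 4.08, AT4G12490 at 3.76, BGLU18 at 3.44, MBP1 at 3.15, JAL23 at 3.14, PAD3 at 3.1 and BHLH101 at 3.09. Those with the lowest were AT3G16670 at −3.26, AT4G33720 at −3.18, AT2G07719 at −2.96, DUR3 at −2.49, HVA22B at −2.42, AT5G10120 at −2.38, RALFL11 at −2.38 and PER1 at −2.35.

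Of 272 groups of 4 arrays, each a named gene in a tissue, 11 (4.04%) had 1 array apart from the others, with a gap to the nearest of them, as a share of the range, over Dixon's critical value for 4 arrays, and chance gives about 1 in 20. In inflorescences these were AT4G33720 on replicate 1 (0.830 of the range), WUS on replicate 3 (0.854) and HSP70 on replicate 4 (0.964). In seedlings they were AIG1 (0.871), PCR1 (0.873), bHLH39 (0.845) and XTH5 (0.925) on replicate 1, PABN3 on replicate 2 (0.916), OLEO2 (0.839) and XTH12 (0.935) on replicate 3, and STK on replicate 4 (0.928).

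Among probes without a locus, which the comparisons did not use, 2410 passed the filter, and limma called 809 changed in inflorescences and 956 in seedlings.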

How the results depend on the processing

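The test against a change of 1.5-fold was chosen after seeing the data, and all other alternatives before. Under 15 settings of the processing, no called list or named gene turned its direction, and the totals of genes stayed within 1.5 times their value except for the tissue difference, which fell to 2939 genes under median centring. The counts ranged from 8842 to 12596 in inflorescences and from 10833 to 12827 in seedlings. Against a 1.5-fold change, 562, 883 and 354 genes passed in inflorescences, in seedlings and for the difference, by construction fewer. The correlation of the tissue effects was 0.510 with the software's log ratio, 0.565 with median centring and 0.611 with the strict filter, which tests 17718 genes; its jackknife SE was 0.0201. For the software's log ratio and median centring, the cause was not tested. Median centring lowered the share of higher genes among those called, from 48.7% to 39.0% in inflorescences, from 49.4% to 32.4% in seedlings and from 50.7% to 36.4% for the difference, where the share also fell below 50% in 4 other settings, and the cause was not tested. Aquantile normalization leaves log ratios as they are and tests nothing.

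With each array left out in turn, the counts ranged from 9291 to 12638 in inflorescences, from 10331 to 12388 in seedlings and from 4930 to 7803 for the difference, the correlation from 0.527 to 0.553 and the called values of named genes from 257 to 261 of 261. Shifted lists ranged from 6 to 10 in inflorescences (10 without inflorescence replicate 4, cause not tested), from 12 to 13 in seedlings and from 9 to 12 for the difference. Under the strict filter, 191 of the 261 called values of named genes were still tested, and all were called. Over all settings, list calls were lost 17 times under the processing settings and 4 times with an array left out, each named beside its list, and gained 31 and 20 times. Calls of named genes were lost 39 and 17 times and gained 3 times under the processing settings.

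Replicate numbers are shared by the tissues but were not shown to pair them. With the number as a block, 11056 genes changed in inflorescences (10867 of them also called without it), 11951 in seedlings (11819) and 6150 differed (6012), with 8, 13 and 10 lists shifted. Signal over background, at 2.63 to 5.48, limits what can be said of transcripts near background, such as PAPS3 in seedlings.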

Other observations

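The families by symbol prefix and the loci on chromosome 2 were chosen after the data had been seen. The test of iron genes was chosen after the main results but before most of its own values had been seen.

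Iron genes outside the fixed list also rose in seedlings. The set of 11 was written down to test the hypothesis that the iron-deficiency response was induced as a whole in mutant seedlings, before their values, except that of BHLH101, had been seen. Of the 11, 9 rose in seedlings, with a median log2 ratio of 0.75, against 4 that rose and 2 that fell in inflorescences, with a median of 0.03. The peptide genes IMA1 (AT1G47400) and IMA2 (AT1G47395), which signal iron shortage, rose by 2.71 ± 0.06 and 2.05 ± 0.13, the ferric reductase gene FRO3 by 1.2 ± 0.11, the regulator PYE by 0.85 ± 0.05 and the transporter gene OPT3 by 0.75 ± 0.05. BTS, at 0.09, and CYP82C4, at −0.42, did not pass, nor did FRU (FIT) at −0.07 and FRO2 at 0.05 on the fixed list. The test, induction of the iron-deficiency response as a whole, gave 9 of 11 where at least 50% were asked for. The 9 include BHLH101, whose value had been seen, and of all 21446 loci 6131 rose in seedlings. Since BTS, CYP82C4, FRU and FRO2 did not pass, a rise of the whole response was not shown. An induction of a part of it may underlie the rise, but age went with genotype in these seedlings. There 9 of 14 root markers, among them IRT1 of the fixed iron list, also rose, with a median of 0.62. The fixed iron list lost its call with an estimated correlation (adjusted p = 0.465) and with the strict filter (median 0.07, adjusted p = 0.751), which also drops genes that are dim in inflorescences.

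Families defined by symbol prefix, 332 with at least 6 tested members, were tested with camera and 7 shifted in inflorescences, 13 in seedlings and 12 between tissues. With an estimated correlation none passed, at a smallest adjusted p of 0.927. Of the families that shifted at the preset correlation, aquaporins of the plasma membrane (PIP) had 13 of 19 members higher and 1 lower in inflorescences (adjusted p = 0.0317), and early nodulin-like genes (ENODL) 13 of 18 higher and 2 lower (adjusted p = 0.0317). LSH genes had 6 of 9 lower and 1 higher (adjusted p = 0.0487). In seedlings, sulfate transporters (SULTR) had 8 of 9 members higher (adjusted p = 0.00806), amino acid permeases (AAP) 7 of 8 (adjusted p = 0.0171) and root hair specific genes (RHS) 7 of 8 (adjusted p = 0.0114), in seedlings where the root markers had a median of 0.62. Ketoacyl-CoA synthases of wax and lipid synthesis (KCS) had 11 of 20 lower and 1 higher (adjusted p = 0.0200), and plant defensins (PDF) 9 of 13 higher and 1 lower (adjusted p = 0.0226), of which PDF1.2, PDF1.2b and PDF1.2c, all higher, are also on the fixed jasmonate list. Whether the probes tell PDF1.2, PDF1.2b and PDF1.2c apart was not tested.

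A group of 44 loci on chromosome 2 was picked after AT2G07719 had been seen, by a range of locus numbers that includes it. The range was taken to mark a copy of mitochondrial sequence, but whether each locus lies in that copy was not checked. In inflorescences 30 rose and 2 fell, with a median of 0.35. In seedlings 16 rose and 4 fell, with a median of 0.12. Loci within such a copy would share a block of sequence, so their probes need not be independent. These probes were not tested for reading transcripts of the mitochondrial genome itself.

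Where a locus had more than 1 tested probe (399 loci), the probes were called in opposite directions at 18 loci in inflorescences and 25 in seedlings. The brightest probe stood for the locus in each comparison.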
